A study of Homo sapiens with 10 samples.

How the data were processed

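ZEB1 was profiled by CUT&RUN in 8 libraries, 2 from each of 4 conditions: untreated cells and cells given 300 nM eribulin for 24, 48 or 72 h. A further 2 IgG libraries of untreated cells are part of the 10 samples of the series and were not analysed here. Per the labels, the libraries came from a commercial CUT&RUN assay with an anti-ZEB1 antibody. The sample descriptions also speak of Tn5 fragmentation, which is not a step of CUT&RUN, and which protocol was used was not resolved. The labels' notes name bcl2fastq 2.20.0.422, cutadapt 2.4, Bowtie2 2.2.6, Picard, MACS2 2.1.1, bedtools 2.30.0, featureCounts and deepTools, with the hg38 assembly, and give no role or order for them.

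The deposited count table holds counts, as whole numbers without normalization, for each ZEB1 library over the 52981 consensus sites, and whether reads or fragments were counted is not stated. All of its columns of values were used. The deposited peak lists, 1 per condition, give for each peak a fold enrichment (a ratio) in the layout of MACS2, and -log10 p and -log10 q values of the peak caller. The highest q in the lists was 0.0497. Peak names in the deposited lists carry the name of replicate 1, and some names occur with separate intervals, so each entry looks like a stretch of a replicate 1 peak shared with another list. The consensus intervals equalled the merged union of the 4 lists on chromosomes 1 to 22, X and Y. Peaks on unplaced contigs numbered 333 in control, 383 at 24 h, 351 at 48 h and 286 at 72 h and were left out of it, but the overlaps of whole lists include them.

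Counts in consensus sites summed to between 1130706 and 3561455 per library. The 2 libraries of each condition were compared by a chi-square statistic per degree of freedom over sites with 20 or more counts, where sampling alone gives about 1. Values were below 1 in each condition, and over sites with 320 or more counts they were 0.833, 0.869, 0.937 and 0.984 in control and at 24, 48 and 72 h. Between conditions they lay from 2.06 to 8.55. The libraries of a condition were therefore treated as 1 sample for every statement about conditions. At the depth of the 72 h and control libraries, the test was tried on simulated data with 41224 tested sites: it recovered 9 of 67 sites changed 1.5-fold, 34 of 67 changed 2-fold and 60 of 66 changed 4-fold, with 9 false calls. Only 200 sites were changed, which makes the Benjamini-Hochberg cutoff stricter than in the comparisons below, where many more were called.

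The comparisons used edgeR 4.0.16 (R 4.3.3) with TMM factors, filterByExpr by condition, a robust quasi-likelihood fit of all 8 libraries with condition as the only term, 2-sided F tests and Benjamini-Hochberg adjustment at 0.05. The filter kept 46436 sites. The common dispersion was 9.77e-05, a biological coefficient of variation of 0.00988, which reflects counting noise and not the variation between cultures. Values at single sites are pooled, TMM-scaled CPM, and their 95% intervals are exact binomial intervals of the pooled counts. The tests, the filter, the 14 gene lists, the rule for naming sites and the first group of alternatives below were fixed before the data were examined.

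Genes came from the RefSeq table of GRCh38 patch 14, with 59788 genes, and 445 of 446 list symbols were matched. Because that table gives no strand, the planned distance to a transcription start was replaced by the distance to the nearest end of a gene, whichever end it is. Sites were linked to the protein-coding or microRNA gene with the nearest end within 100 kb, which linked 41042 sites (88.4%) to 14699 genes. For position classes, sites were near a gene end (within 1 kb of an end of a protein-coding, microRNA or long non-coding gene; 28.4%), in a gene body (44.1%) or intergenic (27.5%). Shares of called and other tested sites are given as odds ratios. Peak overlaps were counted with bedtools 2.31.1, any shared base counting, with exact binomial 95% intervals.

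The lists were epithelial junction and polarity genes, epithelial regulators, mesenchymal effectors, EMT transcription factors, YAP, TEAD and AP-1 targets, TGF-beta targets, tubulin and mitosis genes, p53 and cell cycle arrest genes, interferon and innate genes, chromatin regulators, drug response and DNA repair genes, stemness genes, housekeeping promoters, and lineage genes expected to be silent. Each was tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the 14 lists, and again with an estimated correlation. Calls within a list were also adjusted over the list alone. The percentile of each list's median comes from 10000 random lists matched on the number of linked sites and mean count.

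Sites are named by 3 rules. The first takes, per direction, the 10 called sites with the largest log2 fold change among those above the median abundance whose treated libraries lie on the same side of both controls. The second takes the sites with the smallest p of each list, with 2 given per list at most times. The last takes, whatever its p, the site with the highest mean count in or within 10 kb of genes fixed in advance, among them CDH1, EPCAM, ESRP1, CRB3, GRHL2, MIR200C, MIR200B, ZEB1, VIM, CCN1 and CCN2. Not every site that these rules select is reported here. Agreement between times was set against 20 simulations of unchanged groups drawn around the observed control counts and compared with those same counts.

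A background scaling was added after the data were seen. The pileup and the local background at each summit of replicate 1 were recovered from the fold and p of the peak lists, and the lowest background, the genome-wide floor of the peak caller, served as the depth of the library. Among peaks with distinct names and without extreme p, the recovery gave a background for 41375 of 41378 in control, and for all 32442, 21143 and 17307 at the 3 times. It was checked on simulated peaks. Whether an IgG library served as control for the peak caller is not stated. A control shared by all conditions and scaled to each library would give local backgrounds in steps that are the same percent of the floor in each, and this was checked. A first version also corrected for fragment length. It was dropped for the floor alone, which needs fewer assumptions, and both put the counts of treated libraries well below control. Also added afterwards were the 2-fold threshold, libraries summed with an assumed coefficient of variation of 0.2, the matched random lists, camera on 72 h against 24 h, and the shares near chromosome ends (5 Mb), gene density within 500 kb and zinc finger genes.

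The alternatives chosen from the start were DESeq2 size factors, library totals, factors from the third of sites with the lowest counts, the DESeq2 1.42.0 Wald test, no low-count filter, a fit of the compared conditions alone, a replicate block, and leaving out each library. For the other results they were peaks with q below 0.0001, equal list lengths, an overlap of 50%, links within 5 kb, an estimated correlation and a 3 kb window. The comparison with IgG, a fit with all 10 libraries and motif searches were not run, because no IgG counts and no genome sequence were used here. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.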

Results

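ZEB1, a zinc finger repressor that drives the epithelial-mesenchymal transition, was mapped by CUT&RUN in a human breast cancer line that the labels call MDA and describe as lacking the estrogen, progesterone and HER2 receptors. The labels also mention Tn5, an enzyme that CUT&RUN does not use, so the exact protocol is uncertain. In CUT&RUN, an antibody directs a nuclease to the sites a protein occupies, and the released DNA fragments are sequenced. Cells were untreated or received 300 nM eribulin, a microtubule inhibitor used against breast cancer, for 24, 48 or 72 h. Each of these 4 conditions had 2 ZEB1 libraries, and untreated cells also gave 2 IgG libraries, which were not analysed here. All exposure times share the same untreated control, for which no time is given, so exposure and time in culture cannot be told apart. The series title places the work in the study of drug-induced mesenchymal-epithelial transition, and the comparisons ask where ZEB1 signal lay in untreated cells and how it moved with exposure time.

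The count table covered 52981 consensus sites on the hg38 assembly. Total counts in these sites were 3561455 and 3146228 in the control libraries, 1886419 and 1799143 at 24 h, 1346179 and 1380070 at 48 h, and 1207987 and 1130706 at 72 h. The 2 libraries of every condition differed by less than the sampling noise of their counts. Over sites with 20 or more counts, chi-square per degree of freedom was 0.830 in control, 0.886 at 24 h, 0.928 at 48 h and 0.951 at 72 h, where independent draws give a value of about 1 and separate cultures usually more. Each pair was therefore counted as 1 sample (n = 1 per condition), and no value has a replicate check between cultures. Site values are counts scaled to library size (CPM) over the pooled pair, and the 95% intervals cover counting error only. The p-values come from a test on the counts of the libraries. They compare these libraries, not the conditions, and measure technical spread.

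Fewer ZEB1 peaks were called the longer the cells were exposed. The deposited lists held 46483 peaks in control, 33466 at 24 h, 21816 at 48 h and 17941 at 72 h, covering 13397589, 8412504, 5088286 and 4255766 bases. Of the control peaks, 60.9% overlapped a 24 h peak (exact 95% binomial interval 60.5 to 61.3), 40.8% a 48 h peak (40.3 to 41.2) and 34.7% a 72 h peak (34.3 to 35.1). Conversely, 85.6%, 89.1% and 92.7% of the peaks at the 3 times overlapped a control peak. List length set much of this order, since over the 17941 strongest peaks of each list the overlaps with control were 66.3%, 69.2% and 66.0%. A total of 12793 consensus sites held a peak in all 4 conditions, and 15853 in control alone.

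The loss of site counts was not matched by the genome-wide background of the libraries. The background floor that the peak caller used for replicate 1, recovered from its fold and p columns, was 108% of control at 24 h, 101% at 48 h and 95.2% at 72 h. Whether the peak caller was given an IgG control is not stated. Counts in consensus sites per unit of this floor were 49.0% of control at 24 h, 37.5% at 48 h and 35.6% at 72 h. The fold changes that follow were normalised by TMM, which centres the sites on each other, so that higher and lower mean higher and lower relative to the other sites. Scaling to the background floor instead moved the median log2 fold change by -0.93 at 24 h, -1.42 at 48 h and -1.50 at 72 h, and 91.5%, 95.8% and 97.2% of the changed sites were then lower, against 48.9%, 50.2% and 47.5% with TMM. With factors from the third of sites with the lowest counts, those shares were 63.0%, 64.0% and 59.6%.

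**Figure D1:**
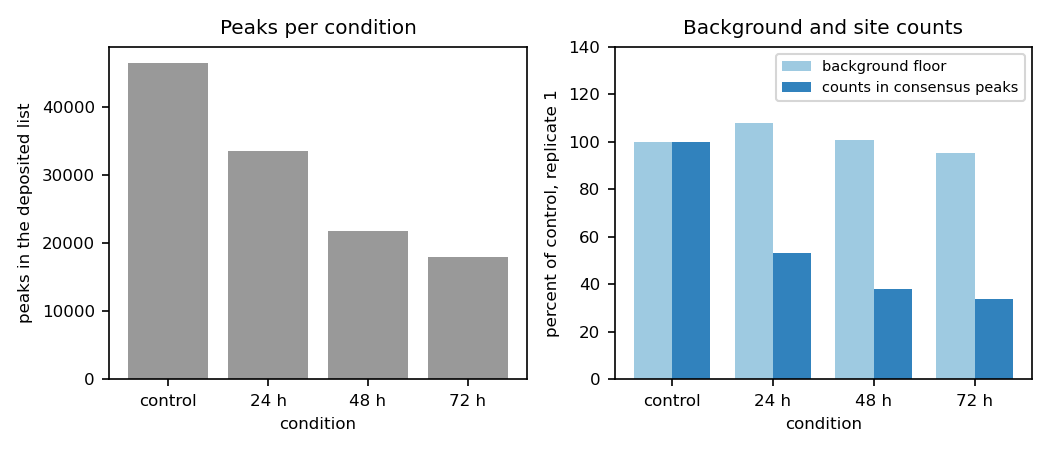
Left, number of peaks in each deposited list (bars, y axis from 0) for control and 24, 48 and 72 h of eribulin. Right, background floor and total counts in consensus peaks of replicate 1, as percent of control: the floor was 95.2% of control at 72 h while the peak number fell from 46483 to 17941.

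The 10 largest losses of ZEB1 signal at 24 h included 3 sites at FOS, 2 at FOSB and 1 at NR4A1. FOS encodes a subunit of the AP-1 transcription factor. Its strongest site (chromosome 14, 75283362 to 75284463, 1682 bp from the nearest gene end) went from 314 CPM in control to 12.6 CPM, a log2 fold change of -4.63 (-5.08 to -4.22; edgeR adjusted p = 1.59e-130). FOSB, another AP-1 subunit, lost signal at chromosome 19, 45476270 to 45476822 (99.6 to 3.94 CPM, log2 -4.64, -5.50 to -3.93) and at 45475307 to 45475939 (152 to 8.94 CPM, log2 -4.08). The site next to NR4A1, an orphan nuclear receptor, fell from 63.7 to 3.15 CPM (chromosome 12, 52059977 to 52060678, log2 -4.31). Sites linked to CAVIN1, a caveola component (log2 -4.40), IQCN (log2 -3.97) and ALOX5AP, a leukotriene synthesis factor (log2 -3.81), fell as well. The others of the 10 lay at further FOS positions (log2 -4.40 and -3.75) and 171219 bp from any linked gene on chromosome 6 (12468272 to 12468555, log2 -3.88).

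The 10 largest gains in fold change, a ranking that favours sites with little ZEB1 in control, spanned several chromosomes. The site next to MIR647 within UCKL1 (chromosome 20, 63941895 to 63942366) went from 2.16 to 54.1 CPM, a log2 fold change of 4.61 (3.87 to 5.54; edgeR adjusted p = 6.53e-50). A site near CXCL17, a mucosal chemokine gene, within the antisense gene LIPE-AS1 (chromosome 19, 42455735 to 42456015) rose from 1.23 to 22.6 CPM (log2 4.12). Sites in the zinc finger genes ZNF566 (chromosome 19, 36449184 to 36449610, log2 3.64) and ZNF582 (56383899 to 56384484, log2 3.54) rose too. Gains of log2 3.84 on chromosome 4 (179110468 to 179110710, far from any linked gene), 3.79 in CHD1L, 3.51 near NIM1K, 3.40 at 84067 bp from SNX19, 3.35 in FGD6 and 3.19 in CENPE, a kinetochore motor gene, completed the 10 largest. All 10 stayed above control with background scaling, which follows from its near-constant shift of -0.93 and is no separate check.

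Across 46436 tested sites, 12467 were lower and 13006 higher at 24 h (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), of which 6282 and 6893 changed at least 2-fold. If separate cultures varied with a coefficient of 0.2, 3633 and 3833 would pass. Calls that were lower lay within 1 kb of a gene end less often than other tested sites (24.5% against 29.9%, odds ratio 0.763), a difference that was small with a 3 kb window (odds ratio 0.960). For calls that were higher, the shares were 29.0% and 28.2% (odds ratio 1.04, which did not pass a Fisher exact test, or 0.882 with a 3 kb window). Sites are not independent of each other. Log2 fold changes at 24 h ran against gene density, with Spearman rho -0.23 across 40601 sites more than 5 Mb from a chromosome end. The median was 0.46 on gene-poor chromosome 4 against -0.44 on gene-dense chromosome 22.

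Among gene lists fixed beforehand, 3 stood below the other sites at 24 h. Sites named by a list gene here and below are linked to it within 100 kb and may lie far from it. Those of SNAI1 (41208 bp away), SYT1 (60007 bp) and RUNX1 (89598 bp) are examples. Of 181 sites linked to TGF-beta targets, 82 fell and 33 rose (84 and 33 adjusted over the list alone). Their median log2 was -0.46, at the 4.52 percentile of matched random lists (limma camera adjusted p = 0.00466, and camera adjusted p = 0.0315 with an estimated correlation). Sites next to each end of BHLHE40, a bHLH repressor gene, fell, from 191 CPM by log2 -2.55 and from 280 CPM by log2 -1.73. The epithelial junction and polarity list had 80 of 190 sites lower and 30 higher (80 and 30 adjusted over the list alone), with a median of -0.38 at the 3.61 percentile (camera adjusted p = 0.00482, and adjusted p = 0.0315 with an estimated correlation). It was led by PARD6B, a polarity complex gene (489 CPM in control, log2 -1.16, -1.28 to -1.05), and a site within KRT8 linked to KRT18, simple-epithelium keratin genes (log2 -1.77). For p53 and cell cycle arrest genes, 44 of 93 sites fell and 16 rose (44 and 16 adjusted over the list alone; median -0.38 at the 8.97 percentile; camera adjusted p = 0.0316, adjusted p = 0.172 with an estimated correlation and 0.0592 with sites linked within 5 kb). A distal MYC site fell (342 CPM, log2 -1.18), and a GADD45A site rose (log2 1.41). The medians of all 3 lists lay inside the central 95% of matched random lists.

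The remaining lists did not pass camera at 24 h. YAP, TEAD and AP-1 targets had 113 of 298 sites lower and 66 higher (113 and 69 adjusted over the list alone; median -0.22), with FOS above and DUSP1, a MAP kinase phosphatase gene, at log2 -2.07 from 320 CPM. With sites linked within 5 kb only, this list did pass (limma camera adjusted p = 0.000675). Over all its linked sites, however, the median lay at the 54.8 percentile of matched random lists. Epithelial regulators had 30 lower and 20 higher of 105 (30 and 19 adjusted over the list alone), among them ELF3 (log2 -1.68) and EHF (log2 -2.69), ETS factors of epithelia. EMT transcription factors had 32 lower and 18 higher of 84 (the same counts adjusted over the list alone), with ETS1 at log2 -1.19 and a SNAI1-linked site at log2 -1.50. Mesenchymal effectors had 44 lower and 53 higher of 180 (the same adjusted over the list alone), with a median of -0.08 and a mean of 0.10. COL1A1 (log2 -1.22) and TPM1 (log2 -1.73) fell. Drug response and DNA repair genes had 36 lower and 29 higher of 92 (37 and 29 adjusted over the list alone), with sites next to MCL1, an anti-apoptotic gene, at log2 -2.53 and -2.13. Interferon and innate genes had 36 lower and 25 higher of 103 (the same adjusted over the list alone), with IFIT3 at log2 2.07 and IRF1 at log2 -1.29. Chromatin regulators had 17 lower and 36 higher of 101 (17 and 35 adjusted over the list alone), with a median of 0.27 that was -0.66 with background scaling. SMARCA4 fell (log2 -1.20), and a site 70414 bp from EED was at log2 1.13, or 0.20 and not passing with background scaling.

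Tubulin and mitosis genes, the set closest to the drug's target, had 19 lower and 30 higher of 92 sites at 24 h (the same adjusted over the list alone), with a median of 0.19 that was -0.74 with background scaling. A site within MAPRE3, a microtubule plus-end gene, was at log2 -1.29 and one 86376 bp from KIF18A, a mitotic kinesin gene, at log2 2.00. Stemness genes had 18 lower and 15 higher of 75 (18 and 14 adjusted over the list alone; median -0.07), with a CD44 site at log2 1.43. Housekeeping promoters had 21 lower and 17 higher of 73 (the same adjusted over the list alone; median 0.01, -0.92 with background scaling), with ACTB at log2 2.64. Lineage genes expected to be silent had 20 lower and 10 higher of 64 (19 and 10 adjusted over the list alone), with PECAM1, an endothelial adhesion gene, at log2 -2.90 and MBP at log2 -0.91.

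The 10 largest losses at 48 h included 2 sites at CCN2 and 1 at FOS. The ALOX5AP site (chromosome 13, 30737780 to 30738220) had gone from 37.8 to 1.91 CPM (log2 -4.26, -5.94 to -3.06; edgeR adjusted p = 6.40e-25), and the strongest CCN2 site (chromosome 6, 131946902 to 131947494) from 78.5 to 11.1 CPM (log2 -2.82, -3.42 to -2.29). CCN2 encodes a matricellular growth factor and is a classic YAP target. SH3TC2 (log2 -3.32), TMIGD1 (log2 -3.19), FOS (log2 -3.09), CRYGN (log2 -2.93), a site 51445 bp from MAP3K1 (log2 -2.90), a further CCN2 site (log2 -2.82) and positions on chromosome 6 (12468272 to 12468555, log2 -3.54) and chromosome 7 (26515502 to 26515849, log2 -3.06) made up the rest of the 10.

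Many of the strongest gains at 48 h lay close to chromosome ends. At TTC34 on chromosome 1, a site at 2677343 to 2677494 went from 3.08 to 68.0 CPM (log2 4.43) and one at 2674483 to 2674744 from 8.17 to 140 CPM (log2 4.09). Others were on chromosome 14 (105745213 to 105745856, log2 4.60), at KIF26A (chromosome 14, 104225309 to 104226047, log2 4.17) and at KCNT1 (chromosome 9, 135758020 to 135758416, log2 4.18). The rest lay on chromosome 8 within DLGAP2 (1377951 to 1378598, log2 4.12), on chromosome 6 (170146098 to 170146420, log2 4.09, and 168941748 to 168942731, log2 3.85), at RIMBP2 (chromosome 12, 130392615 to 130393325, log2 3.83) and at CXCL17 (log2 3.88). Of the 4872 sites at least 2-fold higher, 29.5% lay within 5 Mb of a chromosome end, against 10.6% of other tested sites (odds ratio 3.54). At 24 h, these shares were 11.1% and 12.8%.

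In all, 7844 sites were lower and 7796 higher at 48 h by edgeR, and 3505 and 4872 changed at least 2-fold. Without 48 h replicate 1 or 2, the number lower was 5057 or 4855. With an assumed coefficient of variation of 0.2, 1026 and 2737 passed. Both directions were under-represented within 1 kb of gene ends (21.1% of lower calls against 29.9%, odds ratio 0.628, and 24.0% of higher calls against 29.3%, odds ratio 0.763).

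TGF-beta targets were the only list of the 14 to pass camera at 48 h, with 67 of 181 sites lower and 20 higher (72 and 22 adjusted over the list alone). The median was -0.28, at the 5.98 percentile and inside the central 95% of random lists (camera adjusted p = 0.0162, camera adjusted p = 0.0781 with an estimated correlation). Both BHLHE40 sites were lower (log2 -1.32 and -1.03), the latter not passing with an assumed coefficient of variation of 0.2. YAP, TEAD and AP-1 targets had 83 lower and 38 higher of 298 (86 and 44 adjusted over the list alone), led by FOS (log2 -2.21) and FOSB (log2 -2.33). This list passed with sites linked within 5 kb (limma camera adjusted p = 0.00165). Over all its linked sites, however, the median was -0.15, at the 38.85 percentile of random lists. In the epithelial junction list, 37 sites were lower and 47 higher (40 and 47 adjusted over the list alone), with a median of 0.10 that was -1.32 with background scaling. This median lay at the 98.6 percentile, above the central 95% of random lists, although camera did not pass. PKP3, a desmosomal plakophilin, was at log2 1.96, still above control with background scaling. Epithelial regulators had 26 lower and 12 higher (28 and 13 adjusted over the list alone), with ELF3 at log2 -1.22 and OVOL1, a zinc finger repressor of the mesenchymal state, at log2 2.51. Mesenchymal effectors had 36 lower and 24 higher (34 and 24 adjusted over the list alone), with ITGB3 at log2 -0.84 and COL6A2 at log2 1.33, which was -0.09 with background scaling.

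Lower and higher sites at 48 h numbered 18 and 16 for EMT transcription factors (20 and 16 adjusted over the list alone; SNAI1 log2 -1.25, RUNX1 log2 0.77, the latter -0.65 with background scaling) and 24 and 12 for p53 and arrest genes (the same adjusted over the list alone; a MYC site log2 -2.46, CCNE1 log2 1.84, the latter 0.42 and not passing with background scaling). For interferon genes they were 23 and 12 (the same adjusted over the list alone; CXCL8 log2 -2.02, IFIT3 log2 2.12), and for chromatin regulators 7 and 13 (7 and 11 adjusted over the list alone; KDM5B log2 3.63 from 0.925 CPM, CTBP1 log2 2.89 from 1.54 CPM). Drug response genes had 22 and 14 (24 and 15 adjusted over the list alone; MCL1 log2 -1.60, BCL2L1 log2 -1.25), and stemness genes 20 and 11 (22 and 11 adjusted over the list alone; NOTCH1 log2 2.48). Counts were 17 and 11 for tubulin and mitosis genes (the same adjusted over the list alone; CENPE log2 3.11, MAPRE3 log2 -0.63), 14 and 12 for housekeeping promoters (18 and 12 adjusted over the list alone; GPI log2 2.11) and 12 and 8 for silent lineage genes (the same adjusted over the list alone; PECAM1 log2 -2.11, SYT1 log2 3.26).

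At 72 h, FOS and FOSB sites remained among the lowest. A FOS site at chromosome 14, 75282741 to 75282901 went from 39.6 to 3.13 CPM (log2 -3.63, -4.99 to -2.60; edgeR adjusted p = 5.32e-21), the strongest FOS site to 32.6 CPM (log2 -3.26) and the FOSB sites to 10.3 and 18.8 CPM (log2 -3.27 and -3.01). PECAM1 (chromosome 17, 64326486 to 64326989) fell from 51.3 to 4.47 CPM (log2 -3.50). Further low sites were linked to MIR8079 (log2 -3.50), TTI1 (log2 -3.21), AAGAB (log2 -2.99) and DYM (log2 -2.97), and 1 lay on chromosome 1 at 218823251 to 218823600 (log2 -3.24). The highest gains were in FGD6, a guanine nucleotide exchange factor gene (chromosome 12, 95116896 to 95117121, 1.54 to 40.2 CPM, log2 4.65, 3.76 to 5.81), and at CXCL17 (log2 4.44). ZNF566 (log2 4.08), ZNF582 (log2 3.92), ZNF283 (log2 3.50) and a site within ZNF83 (chromosome 19, 52670055 to 52670414, 7.56 to 122 CPM), all zinc finger genes of chromosome 19, came next, along with CENPE (log2 3.95), GPX5 (log2 3.94), AFAP1 (log2 3.51) and a site linked to FGF2 (log2 3.44). All 10 were above control with background scaling too, which again follows from its near-constant shift of -1.50.

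By edgeR, 7916 sites were lower and 8760 higher at 72 h, with 3972 and 5673 changed at least 2-fold and 1134 and 2884 passing with an assumed coefficient of variation of 0.2. Without 72 h replicate 1, the number lower was 4886. Of the sites at least 2-fold higher, 24.9% lay within 5 Mb of a chromosome end against 10.8% of other tested sites (odds ratio 2.73). Lower calls were within 1 kb of a gene end in 20.1%, other sites in 30.1% (odds ratio 0.582). For higher calls these shares were 26.8% and 28.8% (odds ratio 0.907, or 0.987 with a 3 kb window).

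Sites of the epithelial junction and polarity list stood above the other sites at 72 h, with 73 of 190 higher and 30 lower (77 and 31 adjusted over the list alone), though background scaling put the list below control. The median log2 was 0.29, at the 99.9 percentile of matched random lists, and -1.21 with background scaling, where the median of all tested sites was -1.50 (limma camera adjusted p = 0.0255, adjusted p = 0.0574 with an estimated correlation). LAMB3, a laminin chain of epithelial basement membranes, was at log2 2.14 (1.83 to 2.46) and SDC1, an epithelial proteoglycan, at log2 1.81, or 0.31 and not passing with background scaling. TGF-beta targets fell at 59 of 181 sites and rose at 17 (the same adjusted over the list alone), with a median of -0.27 inside the central 95% of random lists (camera adjusted p = 0.0193, adjusted p = 0.0574 with an estimated correlation). BHLHE40-linked sites were at log2 -1.20 and -1.25. YAP, TEAD and AP-1 targets fell at 99 of 298 and rose at 41 (102 and 46 adjusted over the list alone; median -0.22 at the 6.16 percentile, inside the central 95%; camera adjusted p = 0.0255, adjusted p = 0.0574 with an estimated correlation and 0.0597 with sites linked within 5 kb). Mesenchymal effectors had 44 of 180 lower and 15 higher (43 and 15 adjusted over the list alone), with a median of -0.25 at the 1.33 percentile. Of the settings tried, this list passed with a replicate block only (limma camera adjusted p = 0.0601 without and 0.0498 with it, 0.0803 with an estimated correlation and 0.973 with sites linked within 5 kb), with ITGB3 at log2 -1.09 and COL6A2 at log2 1.92.

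The other lists did not pass at 72 h. Lower and higher sites were 26 and 22 for epithelial regulators (28 and 24 adjusted over the list alone; TFAP2A log2 0.85, or -0.66 with background scaling, EHF log2 -1.08) and 24 and 14 for EMT transcription factors (24 and 16 adjusted over the list alone; SNAI1 log2 -2.12, SOX9 log2 2.13). They were 13 and 14 for p53 and arrest genes (12 and 14 adjusted over the list alone; CCNE1 log2 2.39, PMAIP1 log2 1.34, the latter -0.16 with background scaling), whose median of 0.04 and mean of 0.01 were positive while camera gave the direction as down. Interferon genes had 17 and 21 (18 and 21 adjusted over the list alone; IFIT3 log2 2.83, IRF1 log2 -1.31), chromatin regulators 12 and 15 (10 and 13 adjusted over the list alone; HDAC9 log2 4.20 from 0.617 CPM, ARID1A from 15.0 to 34.4 CPM, the latter log2 -0.30 with background scaling) and drug response genes 22 and 21 (23 and 21 adjusted over the list alone; ERCC1 log2 -1.13, EGFR log2 0.75, the latter -0.75 with background scaling). Counts were 10 and 19 for tubulin and mitosis genes (10 and 18 adjusted over the list alone; CENPE as above, TUBA1C from 11.7 to 50.5 CPM), 15 and 15 for stemness genes (the same adjusted over the list alone; CD44 log2 -1.09 at a distal site, POU5F1 log2 1.14, the latter -0.36 with background scaling), 11 and 17 for housekeeping promoters (the same adjusted over the list alone; GPI log2 1.81, EEF1A1 log2 1.70, the latter 0.20 and not passing with background scaling) and 10 and 11 for silent lineage genes (9 and 11 adjusted over the list alone; KDR log2 1.03, or -0.48 with background scaling).

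**Figure D2:**
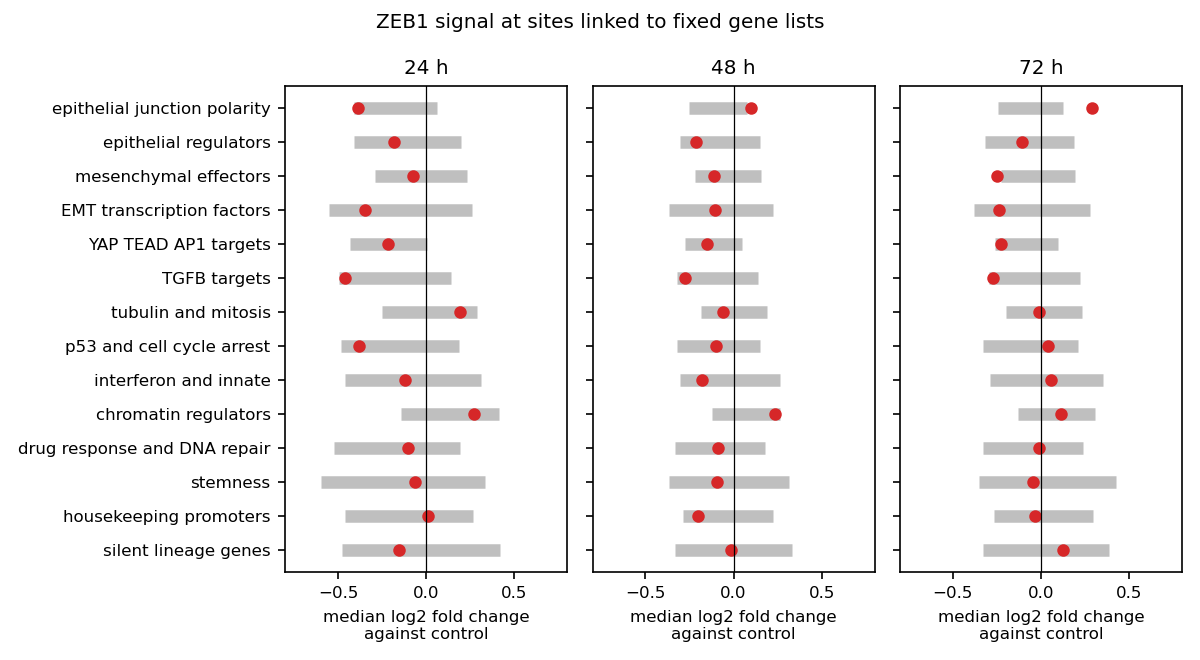
Median log2 fold change of ZEB1 signal against control (x axis, TMM-normalised; red points) at sites linked to each of the 14 lists after 24, 48 and 72 h; grey bars hold the central 95% of 10000 matched random lists. The epithelial junction list lay at -0.38 at 24 h and at 0.29 at 72 h, but at -1.21 with background scaling at 72 h.

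Sites of EMT genes named in advance moved in different directions and at different times. ZEB1's own gene carried a site over its end, within ZEB1 and ZEB1-AS1 (chromosome 10, 31318227 to 31319092), at 73.6 CPM in control, 51.8 at 24 h, 112 at 48 h and 141 at 72 h, log2 -0.51 (-0.75 to -0.26), 0.60 (0.39 to 0.81) and 0.94 (0.73 to 1.15); with background scaling the later values were -0.82 and -0.57. VIM encodes an intermediate filament protein of mesenchymal cells. Its site (chromosome 10, 17228253 to 17228814) rose at 24 h (log2 0.66, or -0.27 with background scaling) and was at 0.02 and -0.38 later, not passing, though the 72 h value passed without 72 h replicate 1 (log2 -0.80). CDH1, which encodes E-cadherin, had its site within the gene body (chromosome 16, 68741850 to 68742072) at 25.4 CPM in control, 6.04 at 24 h, 16.4 at 48 h and 16.5 at 72 h (log2 -2.06, -0.63 and -0.62, each passing by edgeR). The 48 h call for CDH1 was lost without control replicate 1 (log2 -0.57) or 48 h replicate 1 (-0.60) or 2 (-0.63), and the 72 h call without control replicate 1 (-0.57) or 72 h replicate 1 (-0.87) or 2 (-0.42). The site within 10 kb of CRB3, a polarity gene, lay 704 bp from an end of its neighbour SLC25A23 (chromosome 19, 6460140 to 6460853). It fell at 24 h (log2 -0.70) and 48 h (log2 -0.32, not passing without 48 h replicate 1 at -0.26) and was at 0.06 at 72 h, not passing (edgeR adjusted p = 0.582).

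A site 8180 bp from EPCAM, an epithelial adhesion gene (chromosome 2, 47361029 to 47361233), rose from 11.4 CPM to 33.1, 27.9 and 31.3 CPM (log2 1.53, 1.28 and 1.45; with background scaling 0.60, -0.13 and -0.05). Within GRHL2, an epithelial regulator (chromosome 8, 101635814 to 101636014), signal fell at each time (log2 -1.28, -0.86 and -1.40). The 48 h call for GRHL2 rested on single libraries: it was lost without 48 h replicate 1 (log2 -0.36) or control replicate 2 (-0.71), and the value was -1.59 without 48 h replicate 2. MIR200C and MIR200B are microRNA genes whose products target ZEB1. The site within 10 kb of MIR200C lay 5 bp from an end of PHB2 (chromosome 12, 6970599 to 6970918) and did not pass (log2 0.37, -0.48 and -0.73), although the 72 h value passed with library totals (log2 -0.75). The MIR200B site (chromosome 1, 1164734 to 1165103) did not pass at any time (log2 0.03, 0.41 and 0.60). ESRP1, an epithelial splicing factor gene, had 0 consensus sites within 10 kb. CCN2 fell at each time (log2 -3.57, -2.82 and -2.69), whereas the site at CCN1, its paralogue (chromosome 1, 85584259 to 85584704), rose at 24 h (log2 0.39, or -0.54 with background scaling) and did not pass at 48 h (-0.35) or 72 h (-0.26). With an assumed coefficient of variation of 0.2 between cultures, the calls among these genes that still passed were CDH1 at 24 h, EPCAM at 24 and 72 h, and CCN2 at each time.

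**Figure D3:**
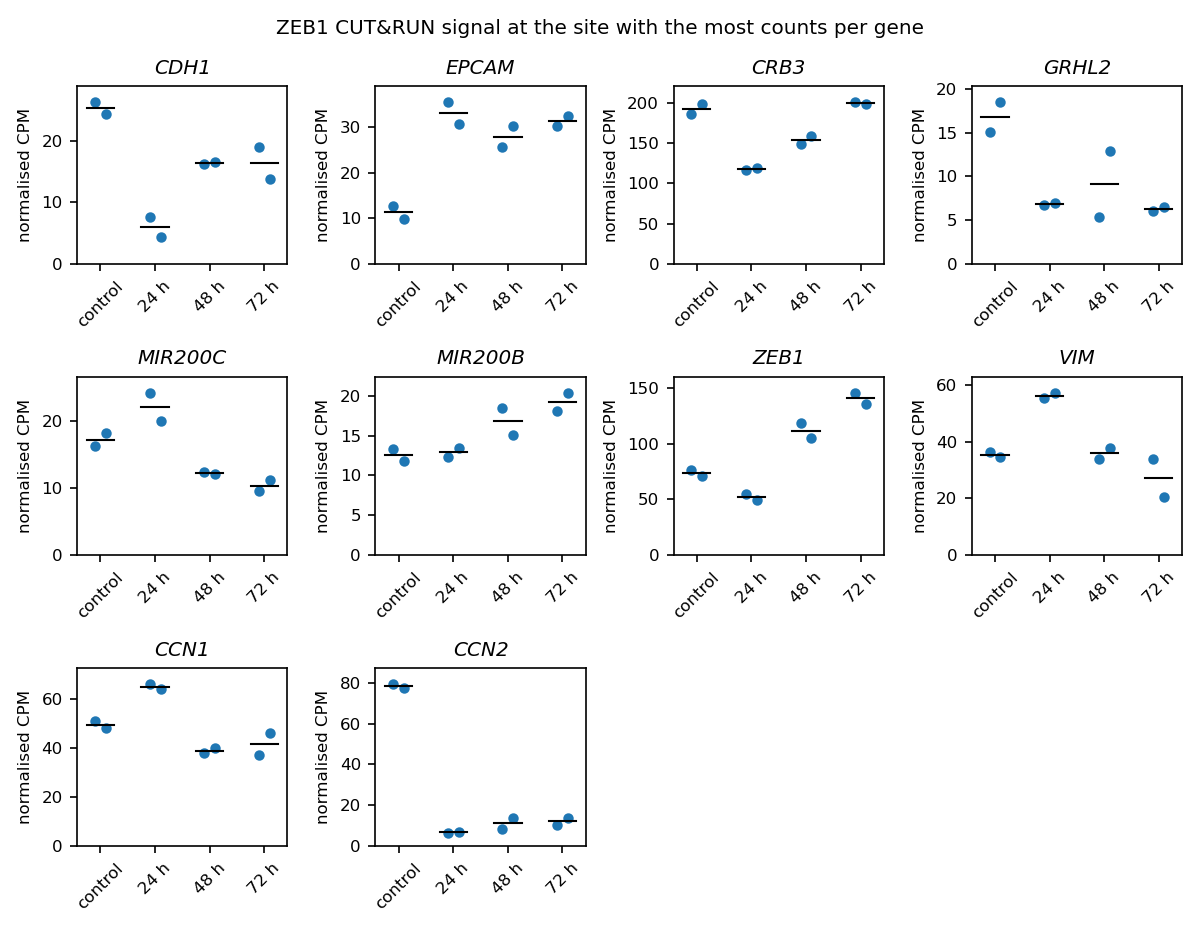
Normalised CPM (y axis, linear from 0) at the site with the highest mean count for 10 of these genes, in control and after 24, 48 and 72 h; points are the 2 libraries of a condition, which differ by less than counting noise, and lines their mean. CCN2 fell from 78.5 to 6.57 CPM at 24 h, and the ZEB1 site went from 73.6 CPM in control to 141 at 72 h.

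Most of the difference between exposure times lay between 24 h and the later times. Tested directly by edgeR, 14478 sites differed between 48 and 24 h (6662 lower and 7816 higher at 48 h), 16637 between 72 and 24 h (7617 and 9020), and 2426 between 72 and 48 h (1118 and 1308). When any library of either time was left out, the lower counts of the comparisons with 24 h shrank more than the higher ones. Of the sites that differed between 48 and 24 h, 46.0% were lower with TMM, 57.6% with library totals and 84.3% with background scaling. Between 72 and 24 h, the share was 45.8% with TMM, 55.7% with library totals and 85.1% with background scaling. Between 72 and 48 h it was 46.1%, 47.3% and 64.7%. Without a library of either time, the 72 to 48 h count was between 1098 and 1202, and with an assumed coefficient of variation of 0.2 it was 1. Without 48 h replicate 2, the 48 to 24 h count was 9214, and without 72 h replicate 1, the 72 to 24 h count was 10756. A total of 4282 sites were lower and 3087 higher at all 3 times, while 730 were lower at 24 h and higher at 72 h and 297 the opposite. In the epithelial junction list, 97 of 190 sites were higher at 72 h than at 24 h and 6 lower. The median difference was 0.71, and 0.14 with background scaling (camera adjusted p = 4.95e-10, adjusted p = 0.00499 with an estimated correlation). Mesenchymal effectors moved the other way, with 16 higher and 41 lower (median difference -0.33, camera adjusted p = 0.00885, and camera adjusted p = 0.0580 with an estimated correlation). These list comparisons were not matched on gene density. Its Spearman rho with the log2 fold change against control was -0.233 at 24 h and 0.000209 at 72 h. Whether gene density contributes to the list differences was not tested.

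Log2 fold changes correlated across sites with Pearson r 0.605 for 24 and 48 h, 0.587 for 24 and 72 h, and 0.825 for 48 and 72 h. Unchanged groups simulated around the observed control counts gave 0.0282, 0.0277 and 0.0387. Because the same control counts were both the centre and the comparison, control noise cancelled and values near 0 were built in. The simulation therefore cannot show how much of r, or of the covariances and shared calls below, comes from the shared controls. The covariances were 0.578, 0.557 and 0.735, against simulated ones of 0.00304, 0.00329 and 0.00585. Of the lower calls, 5956, 5426 and 5116 were shared by these pairs of times, where independent lists give 2106, 2125 and 1337 and simulated unchanged groups 0. Shared higher calls numbered 4385, 4350 and 5583, against 2184, 2454 and 1471. Because the control libraries could not be split with 2 in each part, some of the excess may come from the shared controls; sites are not independent replicates.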

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

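The tests of sequencing depth, of a shared control, of assay yield and of the noise within pairs were chosen after their results were seen, whereas those of the site list, the local background near chromosome ends and gene density were fixed before.

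Exposure times differed from each other when tested directly by edgeR. The sites that differed numbered 14478 between 48 and 24 h, 2426 between 72 and 48 h and 16637 between 72 and 24 h, and 730 sites were lower at 24 h and higher at 72 h while 297 were the opposite. Among the genes named in advance, those whose 24 and 72 h values differed with opposite signs against control were CRB3 (log2 0.77 at 72 h against 24 h), MIR200C (-1.10), ZEB1 (1.44), VIM (-1.04) and CCN1 (-0.65). Against control, the 72 h values of CRB3, VIM and CCN1 and both values of MIR200C did not pass. With background scaling each of the 5 stood below control at both times: log2 was -1.64 at 24 h and -1.44 at 72 h for CRB3, -0.56 and -2.23 for MIR200C, -1.44 and -0.57 for ZEB1, -0.27 and -1.88 for VIM, and -0.54 and -1.76 for CCN1. Each time was counted as 1 preparation, so these differences hold between libraries.

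Peaks on unplaced contigs, which lie outside the consensus sites and were not tested for change, made up a larger share of the lists after treatment. They were 1.14% of the peaks at 24 h, 1.61% at 48 h and 1.59% at 72 h, against 0.716% in control (exact 95% binomial interval 0.642 to 0.797). Their number moved little (333 in control, then 383, 351 and 286), so the share rose because the lists shrank. The overlaps between whole lists include them.

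Counts in consensus sites were lower after eribulin. Lower sequencing depth is argued against by the background floor at 72 h, which was 95.2% of control. Whether an IgG library served as control for the peak caller is not stated; a shared one scaled to each library would give steps of the local background of 1 size relative to the floor, but these were 0.881% of it in control and 0.822%, 0.899% and 0.957% at the 3 times. A site list drawn mostly from control peaks is argued against as well, since over the sites that hold a 72 h peak the log2 ratio of counts per background was -1.39. Lower assay yield in the treated preparations stays open, because each condition was counted as 1 preparation. It cannot be told apart from an effect of the drug, the biological explanation the design names, which was not tested separately. Nor can time in culture be told apart from the drug, since no time is given for the untreated control.

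The libraries of each condition were closer to each other than counting noise. Separately prepared samples would differ by more than sampling, but the highest chi-square per degree of freedom of the 4 conditions was 0.951. Repeat sequencing of 1 preparation would give about 1 if the runs were independent draws. At sites with 320 or more counts the value stayed at 0.984 or less. The test asked only for 1 or less, so it could not reject this candidate. Values well below 1, such as 0.830 in control, are less than independent draws give. Whether repeat sequencing can give them was not tested. No biological explanation applies to this pattern.

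Sites at least 2-fold higher at 72 h were frequent within 5 Mb of chromosome ends, where they numbered 1415 and background scaling left 446 of them higher. More than 5 Mb from chromosome ends, a bias towards gene-dense regions is argued against by a Spearman rho of 0.000209 across 40601 sites. That rho, between gene density and the log2 fold change at 72 h, leaves out the sites within 5 Mb of an end. It therefore cannot decide whether such a bias underlies the gains there. Gene density stands in for GC content, which was not measured. A broad rise of the local background stays open, because the median local background over the floor at the 598 gained peaks was 1.19 times that of other 72 h peaks (bootstrap 95% interval 1.13 to 1.26), between the bounds set for and against it. An effect of exposure time is also open and was not tested separately.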

How the results depend on the processing

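Chosen after the data were seen were background scaling, the 2-fold threshold, and summed libraries with an assumed coefficient of variation of 0.2. Other settings were planned. Unless a reason is given, the cause was not tested.

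Counts of lower and higher sites with DESeq2 size factors, library totals, factors from the sites with the lowest counts, no low-count filter, a fit of the compared conditions alone and a replicate block stayed within 1.5 times the values reported. With a replicate block they were 12447 and 12999 at 24 h, 7831 and 7785 at 48 h and 7913 and 8726 at 72 h, and 14450, 2417 and 16617 between 48 and 24, 72 and 48, and 72 and 24 h. Residuals of libraries with the same replicate number correlated between -0.00461 and 0.0139, so the numbers showed no pairing.

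Background scaling moves sites alike, down in these data. It gave 30183 lower and 2819 higher at 24 h, 38774 and 1718 at 48 h, 38513 and 1108 at 72 h, and 22626 between 48 and 24 h. The DESeq2 Wald test gave 6604 and 6383, 2609 and 4007, and 3061 and 4532 at the 3 times, and 4975, 451 and 6868 between times. The 2-fold threshold, which can only remove calls, gave 6282 and 6893, 3505 and 4872, 3972 and 5673, and 7885, 1096 and 9937. With a coefficient of variation of 0.2, a larger assumed spread, they were 3633 and 3833, 1026 and 2737, 1134 and 2884, and 2191, 1 and 2216. List sites named above that lost their call under it included EED and MBP at 24 h. At 48 h they included ELF3, SNAI1, RUNX1, BCL2L1, ITGB3 and MAPRE3.

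Leaving out each library in turn gave 9742 to 11555 lower and 10058 to 10935 higher at 24 h, 4855 to 6630 and 5917 to 6856 at 48 h, and 4886 to 6963 and 6127 to 7562 at 72 h. Between times the ranges were 9214 to 10659 (48 and 24 h), 1098 to 1202 (72 and 48 h) and 10756 to 13048 (72 and 24 h). The lone library was assumed to vary like the other conditions, and fewer counts are left. Moves of over 1.5 times came without 48 h replicate 1 (5057 lower at 48 h) or 2 (4855, and 9214 between 48 and 24 h) and without 72 h replicate 1 (4886 lower at 72 h, 10756 between 72 and 24 h). Between 72 and 48 h, each library of either time did so (1202 and 1167 without 48 h replicates 1 and 2, 1133 and 1098 without 72 h replicates 1 and 2).

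The share of control peaks overlapped at 24, 48 and 72 h was 59.9%, 37.9% and 31.6% with q below 0.0001, 66.3%, 69.2% and 66.0% with equal list lengths, where list length no longer sets the overlap, and 50.7%, 28.1% and 22.1% with an overlap of 50%, which can only lower it. With library totals, r was 0.605 for 24 and 48 h, 0.587 for 24 and 72 h and 0.825 for 48 and 72 h, as with TMM. Another scaling moves all sites by a near-constant amount, which leaves r unchanged, so this is no separate check.

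With a 3 kb window, the odds ratio near a gene end was 0.960 for lower calls at 24 h and 0.987 for higher calls at 72 h, where the difference no longer passed, and 0.882 for higher calls at 24 h, on the other side of 1 from 1.04, which had not passed.

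Lists passing camera numbered 3, 1 and 3 at the 3 times. With an estimated correlation they were 2 at 24 h, 0 at 48 h and 0 at 72 h, with links within 5 kb 3, 2 and 2, and with a replicate block 3, 1 and 4. At 24 h with links within 5 kb, p53 and cell cycle arrest genes no longer passed (adjusted p = 0.0592) and YAP, TEAD and AP-1 targets did (adjusted p = 0.000675, limma camera). At an estimated correlation, the smallest camera adjusted p was 0.0781 at 48 h and 0.0574 at 72 h. The estimates for the passing lists lay between -0.00481 and 0.0087, below the preset 0.01. The larger p therefore does not come from a stronger correlation between sites. These estimates rest on paired libraries that differ by less than counting noise, so they cannot measure correlation across cultures.

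Of the 169 values at named sites, background scaling reversed 14 that had passed: EPCAM at 48 h (-0.13) and 72 h (-0.049), ZEB1 at 48 h (-0.82) and 72 h (-0.57), VIM (-0.27) and CCN1 (-0.54) at 24 h, COL6A2 (-0.086) and RUNX1 (-0.65) at 48 h, and TFAP2A (-0.66), PMAIP1 (-0.16), ARID1A (-0.30), EGFR (-0.75), POU5F1 (-0.36) and KDR (-0.48) at 72 h. Not all of the 14 passed in the new direction: COL6A2 at 48 h did not (edgeR adjusted p = 0.694 with background scaling). Values that had not passed changed sign too: CRB3 at 72 h (-1.44), MIR200C at 24 h (-0.56), MIR200B at the 3 times (-0.90, -1.01 and -0.90) and VIM at 48 h (-1.40). Background scaling also ended 4 calls and added 8. The other settings gave 1999 values, of which 0 that had passed reversed, 48 no longer passed and 10 newly passed; the assumed coefficient of variation ended 31 calls and the DESeq2 Wald test 6.

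Without 1 library, these called values moved by over 1.5-fold and still passed. Without control replicate 1, they were MIR647 (5.25), the chromosome 4 site (5.15), CHD1L (4.73) and CENPE (3.84) at 24 h, CENPE (3.79) and NOTCH1 (1.90) at 48 h and CENPE (4.62) at 72 h, and without control replicate 2 the chromosome 4 site (3.19) and NOTCH1 (3.33). Without 24 h replicate 1, CAVIN1 (-5.28), FOS (-5.20 and -5.11), NR4A1 (-3.69), ALOX5AP (-4.48) and PECAM1 (-3.54) moved, and without replicate 2 NR4A1 (-5.33) and FOS (-3.10). At 48 h these were the chromosome 6 site (-4.33), CRYGN (-4.41) and MYC (-4.69) without replicate 1, and the chromosome 7 site (-3.99), CRYGN (-2.18), MYC (-1.59) and GRHL2 (-1.59) without replicate 2. At 72 h they were AAGAB without replicate 1 (-2.14) or 2 (-4.96) and TTI1 without replicate 2 (-3.83).

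Depth limits what can pass. On simulated data at the depth of 72 h and control, 13.4% of sites changed 1.5-fold were recovered, 50.7% of those changed 2-fold and 90.9% of those changed 4-fold. The all-library fit with IgG, the test against IgG and the motif searches were not run.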

Other observations

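The comparison of zinc finger genes with other sites of chromosome 19 was added after the data were seen, with bounds set for and against. That of chromosome 19 with other chromosomes, the shares near chromosome ends and the comparison of lists at 72 h against 24 h were also chosen after the data were seen.

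Sites at zinc finger genes of chromosome 19 were among the largest gains. Of 340 tested chromosome 19 sites linked to ZNF-named genes, 11.8% were at least 2-fold higher at 24 h, against 7.65% of the 1987 other sites of that chromosome (odds ratio 1.61, and 1.14 at 48 h and 1.27 at 72 h, where the difference did not pass a Fisher exact test). The odds ratio of 1.61 fell between the bounds set for and against a chromosome-wide gain, so that comparison was undecided. Only the part chosen afterwards argues against such a gain. There, the other sites of chromosome 19 were called less often than such sites on other chromosomes (15.2%, odds ratio 0.461). The share at ZNF genes was also below 15.2%, so these sites did not gain more often at 24 h than sites in general. No biological explanation was tested.

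Sites at least 2-fold lower were scarce near chromosome ends at the later times. At 48 h, 7.82% of them lay within 5 Mb of an end against 13.0% of other tested sites, and at 72 h 7.70% against 13.0%, whereas at 24 h the shares were 12.8% and 12.5%.

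Between 72 and 24 h, p53 and cell cycle arrest genes had 28 of 93 sites higher and 7 lower, a median difference of 0.27 that was -0.29 with background scaling (limma camera adjusted p = 0.0448, and adjusted p = 0.259 with an estimated correlation). Gene density was not matched here either.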
